A study of Arabidopsis thaliana with 10 samples.

How the data were processed

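Roots of Arabidopsis thaliana were compared before and after inoculation with zoospores of Phytophthora parasitica, an oomycete that infects roots. The labels give a mock-inoculated control at 0 h and roots inoculated for 2.5, 6, 10.5 and 30 h, with 2 arrays per group and 10 arrays in all. The plants are named Col-8 in one label and Col-0 in another, so the accession is given here only as Columbia. RNA was extracted with a column kit and biotin-labelled in a single cycle, per the labels' protocols, and each sample was hybridised to 1 Affymetrix ATH1 array.

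The values are MAS5 signal intensity on a linear scale, scaled by the authors so that the trimmed mean of each deposited array, with 2% taken off either end, lay at about 100. MAS5 and GCOS are named in the submitters' processing notes without versions. The values were used as deposited, with no further normalisation. Of 22810 probe sets, 64 control probe sets were left out of the tests and used only for the quality measures. Array values carry no read depth, so precision is limited by the number of arrays, which is 2 per group.

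Values were transformed as log2 of the signal plus 16, and changes are on that scale, which understates the change of dim genes. Probe sets whose mean over the 10 arrays lay at or above the 30th percentile, a signal of 12.4, were kept, which left 15922. A linear model with 1 coefficient per group was fitted to all 10 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean intensity. It had 5 residual degrees of freedom and 3.67 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each comparison, 2-sided, and a probe set was called at an adjusted p under 0.05. The comparisons were each inoculated time against control, each time against the time before it, and limma's F-test over the 4 comparisons with control. These choices, the gene lists and the rule for named genes were fixed before the data were examined; the comparison of 30 h with 2.5 h and the symbol families were added afterwards. With 2 arrays against 2, an exact permutation test of a single gene cannot give a p below 1/3, so single-gene tests rest on the spread shared across genes. P-values measure the spread between these samples, since the labels do not say whether replicates are separate cultures.

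The titles number the arrays of each group Rep1 and Rep2. Differences between replicate 1 and replicate 2 correlated across probe sets in each of the 10 pairs of groups, with coefficients from 0.25 to 0.59, so the numbers pair the samples. The planned model has no replicate term. A model with the replicate number as a block (4 residual and 5.77 prior degrees of freedom) was fitted beside it and is called blocked below. Simulated data for 30 h against control held independent normal noise, with the spread taken from the blocked fit. Each probe set's mean replicate difference, the same in every group, and the changes were added to that noise. The changes were put into 200 of 15922 probe sets, 100 of each size, at all 4 inoculated times. The unblocked model recovered 3.4% of genes changed 2-fold and 67.6% of genes changed 4-fold, with 0.3% false calls. The blocked model recovered 43.8% and 96.8%, with 8.8% false calls. This setting meets the assumptions of the blocked model, so it does not show how the models compare on the real arrays. The share recovered depends on how many genes change, and 2070 probe sets were called at 30 h in the real data. The simulated shares therefore do not give the sensitivity there.

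Probe sets were named from a table that links them to genes, with symbols from the RefSeq annotation. Of the 22746 probe sets other than controls, 13513 name exactly 1 gene, 503 name several and 8730 have no name there. A named gene without a symbol is given by its locus identifier. No genome build is stated for the array, so no coordinates are given. Per comparison with control, the 8 largest rises and 8 largest falls were named among called probe sets that name 1 gene, whose arrays do not overlap between the groups and whose higher group averages a signal of 100 or more. Between successive times, 5 in each direction were named, or the 5 smallest p-values where none was called. For each fixed list, up to 4 called members with the smallest p were named, or up to 2 members with their values where none was called. A gene with several probe sets is represented by the brightest.

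The 29 fixed gene lists hold 453 genes, of which the naming table covers 67, so most members could not be looked up and 10 lists had the 3 or more tested members needed for a test. These were tested with limma's camera at a preset correlation between genes of 0.01, with the Benjamini-Hochberg adjustment over 70 tests. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. Tested on simulated data, camera detected a shifted list and called 0 of 20 unchanged lists. Those lists were longer than the real ones and their noise was independent between genes. In the real lists the estimated correlation reached 0.824, so the simulation does not show that the preset value limits false calls here. Overlaps of calls between times were compared with independent lists, and repeated with a separate control array for each time of a pair. The 20 planned simulations of unchanged groups against shared controls hold no changes, so they give chance with no effect and not the part that shared controls add to real calls.

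Alternatives fixed in advance were quantile normalisation, median centring, and pseudocounts of 1 and 64. Further ones were no filter on dim probe sets, a filter at the 50th percentile, variances without an intensity trend, and only the 4 arrays of the groups compared. Others were the replicate block, a minimum change of 2-fold, only probe sets that name exactly 1 gene, and leaving out each array in turn. Scaling on the hybridisation spike-ins, median centring with the block, leaving out both 30 h or both 2.5 h arrays, leaving out probe sets of plastid-encoded genes and pseudogenes, and splitting the control arrays between the times of a pair were added after seeing the data.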

Results

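Gene expression was measured in Arabidopsis roots infected by Phytophthora parasitica in a compatible interaction, in which the pathogen colonises the host. Mock-inoculated roots at 0 h served as control, and inoculated roots were sampled at 2.5, 6, 10.5 and 30 h, with 2 arrays at each time. There is no mock sample at the later times, so time after inoculation and time of day changed together in the comparisons with control. The plants had a photoperiod of 8 h. If all roots were inoculated together, 6 h and 30 h fall at the same time of day, but these were not compared directly. Signals are given as mean ± SD of 2 arrays (n = 2) and changes as log2 of the signal plus 16, which understates the change of dim genes, with their SE from the fitted model.

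Several quality measures moved with time. The ratio of the GAPDH probe set at the 3' end to that at the 5' end, which rises as RNA is shortened or less fully copied, was 1.37 ± 0.19 in control, 1.42 ± 0.26 at 2.5 h, 1.67 ± 0.043 at 6 h, 2.18 ± 0.06 at 10.5 h and 2.54 ± 0.257 at 30 h. The spike-ins added at hybridisation had a mean signal of 499 ± 76.6 in control, 371 ± 1.41 at 2.5 h and 874 ± 128 at 30 h. The median probe set changed by -0.12, -0.209, -0.178 and -0.168 against control at 2.5, 6, 10.5 and 30 h on the log2 scale, and the changes below are to be read against these shifts. The first principal component, with 46.2% of the variance, separated control from inoculated arrays, and the second, with 19.1%, separated the replicate numbers.

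**Figure D1:**
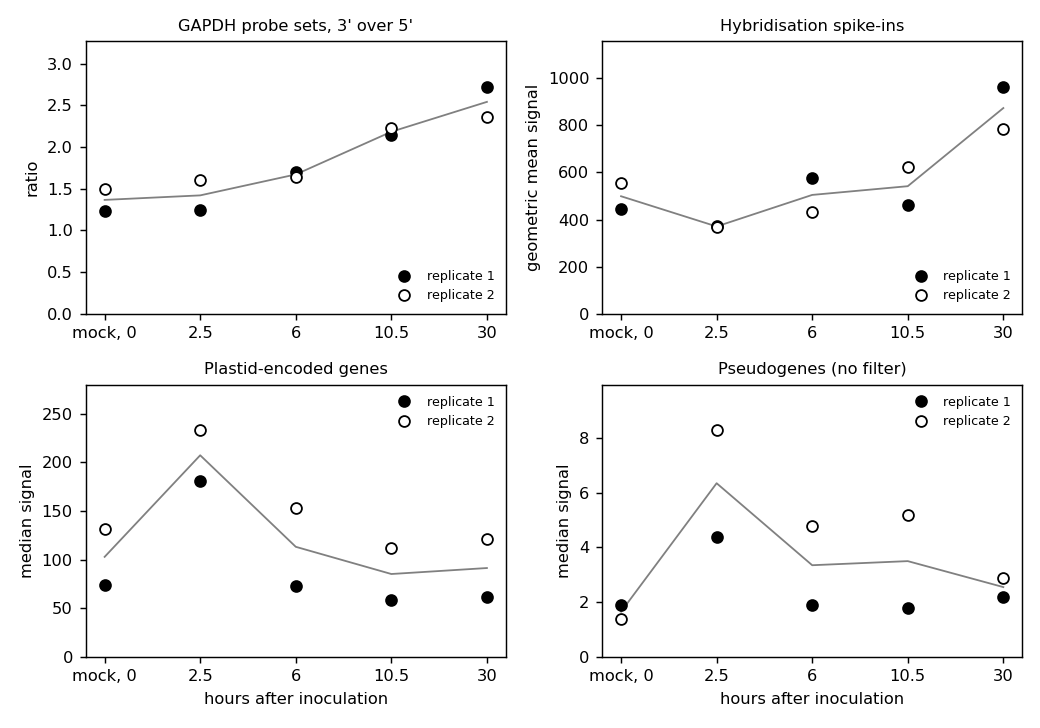
Ratio of the GAPDH 3' to 5' signals, geometric mean signal of the hybridisation spike-ins, and median signal of plastid-encoded genes and of pseudogenes (without the filter on dim probe sets), each on a linear axis by hours after inoculation (0 is the mock control). Points are arrays (filled, replicate 1; open, replicate 2) and lines join the group means; the GAPDH ratio ranges from 1.37 in control to 2.54 at 30 h.

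The first comparison asked what had changed in roots 2.5 h after inoculation. Several genes with low signals in mock roots had far higher ones at 2.5 h. AT1G26380, an FAD-linked oxidoreductase, was at 15.2 ± 13.2 in control and 1915 ± 569 at 2.5 h (log2 change 5.99, SE 0.35, adjusted p = 0.000192). Its neighbour AT1G26410, of the same enzyme family, was at 6.8 ± 7.6 and 408 ± 234. The secreted peroxidases AT5G39580 (50.9 ± 21.8 to 1557 ± 142) and AT1G14550 (1.8 ± 2.1 to 493 ± 180) rose by 4.59 and 4.79; the control signal of AT1G14550 lies far below the 16 added before taking logs, so the size of its change depends on that number. AT2G23270 rose by 5.11, AT4G28085 by 4.32, AT3G18250 by 4.28 and AT5G48430 by 5.55, the last from 138 ± 181 to 4007 ± 92.9. Among the falls, GH3.17, which conjugates auxin to amino acids, went from 535 ± 127 to 83.6 ± 20.0 (log2 change -2.46, SE 0.41, adjusted p = 0.0123). UGT72E2, a glucosyltransferase of lignin precursors, went from 1178 ± 475 to 281 ± 88.4 (-1.98, SE 0.43, adjusted p = 0.0364). The cytochrome P450 gene CYP71B26 changed by -1.78, AT5G17340 by -2.92, AT3G43110 by -2.12, AT2G04460 by -2.06, AT1G72200 by -1.91 and AT4G33960 by -1.88. In all, 690 of 15922 probe sets were called, 594 higher and 96 lower. Within each replicate number the 2.5 h array also had the highest median signal of plastid-encoded genes and of pseudogenes. Without these probe sets 657 were called (563 higher and 94 lower). The blocked model called 1650 (1187 higher and 463 lower), and scaling on the spike-ins gave 985 higher and 12 lower. Median centring ended the call of AT2G04460 (adjusted p = 0.0635), as did no filter on dim probe sets and no intensity trend. Quantile normalisation ended the calls of AT2G04460 and AT3G43110, and a pseudocount of 1 also that of AT5G17340. The count was 422 without control replicate 1, 292 without 2.5 h replicate 1 and 443 without 2.5 h replicate 2. Of the 16 named genes 7, 10 and 10 kept their call. Without control replicate 1 the lost calls were AT5G48430 (3.84), AT5G17340 (-2.33), GH3.17 (-2.23), AT3G43110 (-1.76), AT2G04460 (-1.75), UGT72E2 (-1.56), AT1G72200 (-1.64), AT4G33960 (-1.83) and CYP71B26 (-1.57), and kept but moved by over 1.5-fold was AT3G18250 (3.45). Without control replicate 2 the lost calls were AT3G43110 (-2.47) and AT2G04460 (-2.38), and kept but moved by over 1.5-fold were AT5G48430 (7.27), AT3G18250 (5.12) and AT5G17340 (-3.51). Without 2.5 h replicate 1 the lost calls were AT5G48430 (5.53), GH3.17 (-2.26), AT2G04460 (-2.18), UGT72E2 (-1.67), AT4G33960 (-1.56) and CYP71B26 (-1.43), and kept but moved by over 1.5-fold were AT1G26410 (4.73) and AT3G43110 (-2.76). Without 2.5 h replicate 2 the lost calls were AT5G48430 (5.57), AT5G17340 (-2.60), AT3G43110 (-1.47), AT2G04460 (-1.95), UGT72E2 (-2.29) and AT1G72200 (-1.44), and kept but moved by over 1.5-fold was AT1G26410 (3.54). AT3G43110 and AT2G04460 were also lost without any 1 of the 10.5 h and 30 h arrays (adjusted p from 0.0562 to 0.0847), and UGT72E2 without either 30 h array (0.0736 and 0.073).

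At 6 h the same oxidoreductase gene, AT1G26380, had reached 3668 ± 84.8 (log2 change 6.95, SE 0.35, adjusted p = 3.43e-05). The lectin gene AT3G16530 was at 75.5 ± 24.9 in control and 3853 ± 724 at 6 h (5.42, SE 0.28, adjusted p = 3.43e-05). The peroxidase AT5G39580 rose by 5.40, and the peroxidase AT3G03670 by 6.46, the latter from 4.5 ± 3.7 to 2061 ± 1481. AT4G37290, which encodes the precursor of a PIP peptide, rose from 6.4 ± 3.4 to 930.0 ± 379. AT2G23270 rose by 6.10, AT3G29970 by 5.38 and AT4G28085 by 5.36. Among the genes named by the rule, the largest fall was that of OCT1, an organic cation and carnitine transporter, from 1931 ± 1106 to 123 ± 61.4 (-3.76, SE 0.77, adjusted p = 0.017). AT4G24780, a pectate lyase, fell from 413 ± 308 to 36.5 ± 4.5. GH3.17 changed by -2.77, and AT1G14960, AT5G20700, AT4G30670, AT5G62340 and AT5G17340 by -3.19, -3.01, -2.99, -2.86 and -2.85. In all, 2039 probe sets were called, 1081 higher and 958 lower, and 4259 with the block (1709 higher and 2550 lower). The share of falls depended on the scaling, with 1081 higher and 576 lower after quantile normalisation, 1352 higher and 389 lower after median centring, and 743 higher and 244 lower on the spike-ins. Median centring ended the call of AT4G30670 (adjusted p = 0.065), as did quantile normalisation and no filter on dim probe sets. A pseudocount of 1 ended the calls of AT4G24780, AT4G30670, AT5G17340 and AT5G62340. The count was 818 without control replicate 1, 722 without 6 h replicate 1 and 844 without 6 h replicate 2. Of the 16 named genes 11, 10 and 10 kept their call. Without control replicate 1 the lost calls were AT3G03670 (6.65), OCT1 (-3.15), AT4G30670 (-2.67), AT5G62340 (-2.66) and AT4G24780 (-2.01), and kept but moved by over 1.5-fold were AT3G29970 (6.34), AT1G14960 (-2.09) and AT5G17340 (-2.26). Without control replicate 2 the lost calls were AT3G03670 (6.28) and AT4G30670 (-3.31), and kept but moved by over 1.5-fold were AT3G29970 (4.42), OCT1 (-4.37), AT1G14960 (-4.30), AT5G17340 (-3.45) and AT4G24780 (-3.63). Without 6 h replicate 1 the lost calls were AT3G03670 (5.66), OCT1 (-4.23), AT1G14960 (-3.06), AT4G30670 (-3.38), AT5G62340 (-3.0) and AT4G24780 (-2.73), and kept but moved by over 1.5-fold was GH3.17 (-2.09). Without 6 h replicate 2 the lost calls were AT3G03670 (7.26), OCT1 (-3.29), AT1G14960 (-3.33), AT4G30670 (-2.60), AT5G62340 (-2.72) and AT4G24780 (-2.91), and kept but moved by over 1.5-fold was GH3.17 (-3.45). AT4G30670 was also lost without either 30 h array (adjusted p = 0.0671 and 0.0668).

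At 10.5 h, AT1G26380 was at 3181 ± 432 (log2 change 6.74, SE 0.35, adjusted p = 4.52e-05). CCOAMT, which methylates caffeoyl-CoA on the way to lignin and related phenolics, was at 200 ± 255 in control and 3674 ± 1101 at 10.5 h (4.93, SE 0.93, adjusted p = 0.0121). The lectin AT3G16530 rose by 5.22 and the peroxidases AT5G39580 and AT3G03670 by 5.19 and 5.54, with AT3G03670 at 1990 ± 2500 and thus far apart between its arrays. AT2G23270 rose by 6.08, AT4G28085 by 5.22 and AT3G29970 by 5.11. OCT1 remained low at 178 ± 197 (-3.72, SE 0.77, adjusted p = 0.0183). The pectate lyase AT4G24780 was at 21.9 ± 27.9 (-3.51, SE 0.62, adjusted p = 0.00923). AT1G64590 fell from 3073 ± 626 to 397 ± 25.0. AT5G07030, AT5G62340, AT5G17340, AT5G20700 and AT4G30670 changed by -3.48, -3.19, -3.15, -3.01 and -2.93. In all, 1971 probe sets were called, 1022 higher and 949 lower, and 4343 with the block (1765 higher and 2578 lower). The split was 1063 higher and 654 lower after quantile normalisation, 1294 higher and 457 lower after median centring, and 623 higher and 376 lower on the spike-ins. Median centring ended the call of AT4G30670 (adjusted p = 0.0662), as did quantile normalisation, a pseudocount of 1 and no filter on dim probe sets. A pseudocount of 64 ended that of AT3G03670. The count was 762 without control replicate 1, 1030 without 10.5 h replicate 1 and 637 without 10.5 h replicate 2. Of the 16 named genes 10, 15 and 10 kept their call. Without control replicate 1 the lost calls were AT3G03670 (5.73), OCT1 (-3.11), AT4G24780 (-2.71), AT5G07030 (-2.78), AT5G62340 (-2.99) and AT4G30670 (-2.61), and kept but moved by over 1.5-fold were AT3G29970 (6.08), CCOAMT (3.19) and AT5G17340 (-2.55). Without control replicate 2 the lost calls were AT3G03670 (5.36) and AT4G30670 (-3.25), and kept but moved by over 1.5-fold were AT3G29970 (4.15), CCOAMT (6.67), OCT1 (-4.34), AT4G24780 (-4.32), AT5G07030 (-4.19) and AT5G17340 (-3.74). Without 10.5 h replicate 1 the lost call was AT3G03670 (3.55), and kept but moved by over 1.5-fold were AT3G29970 (5.78), OCT1 (-5.02), AT4G24780 (-4.35), AT5G07030 (-4.12), AT5G62340 (-3.90) and AT4G30670 (-3.75). Without 10.5 h replicate 2 the lost calls were CCOAMT (4.62), OCT1 (-2.42), AT4G24780 (-2.68), AT5G07030 (-2.84), AT5G62340 (-2.49) and AT4G30670 (-2.11), and kept but moved by over 1.5-fold were AT3G03670 (7.54) and AT3G29970 (4.44). AT3G03670 was also lost without either 30 h array (adjusted p = 0.0536 and 0.0533), and AT4G30670 without any 1 of the 6 h and 30 h arrays (0.0593 to 0.0712).

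At 30 h the named genes were partly different. AT1G26380 was still at 3394 ± 808 (log2 change 6.82, SE 0.35, adjusted p = 5.28e-05). The peroxidase AT5G06730, at 47.1 ± 4.9 in control, had reached 2498 ± 489 (5.31, SE 0.20, adjusted p = 2.35e-05). The cytochrome P450 gene CYP71B22 rose from 6.5 ± 7.2 to 887 ± 318, the asparaginase gene ASPGB1 from 18.3 ± 7.7 to 1094 ± 118 and the extensin gene AT1G26240, a cell wall protein, from 29.2 ± 0.6 to 1555 ± 951. AT2G15780 rose by 5.20, AT3G29970 by 5.16 and the peroxidase AT3G03670 by 5.11. Other peroxidases fell. AT1G30870 went from 385 ± 228 to 21.0 ± 14.7 (-3.37, SE 0.66, adjusted p = 0.0141), AT3G49960 went from 227 ± 108 to 8.2 ± 4.6 (-3.26, SE 0.75, adjusted p = 0.025) and AT5G17820 went from 659 ± 388 to 54.6 ± 10.0 (-3.13, SE 0.59, adjusted p = 0.0124). AT1G52070, AT1G14960, AT5G44020, AT1G67330 and AT5G17340 changed by -3.89, -3.52, -3.43, -3.32 and -3.24. In all, 2070 probe sets were called, 1073 higher and 997 lower, and 4377 with the block (1736 higher and 2641 lower). The split was 1070 higher and 651 lower after quantile normalisation and 1360 higher and 430 lower after median centring. On the spike-ins, which were brightest at 30 h, it was 460 higher and 8134 lower. Quantile normalisation, a pseudocount of 64 and no filter on dim probe sets each ended the call of AT3G03670. The count was 727 without control replicate 1, 514 without 30 h replicate 1 and 790 without 30 h replicate 2. Of the 16 named genes 10, 8 and 12 kept their call. Without control replicate 1 the lost calls were AT3G03670 (5.30), AT1G52070 (-3.10), AT5G44020 (-2.75), AT1G30870 (-2.75), AT3G49960 (-2.79) and AT5G17820 (-2.51), and kept but moved by over 1.5-fold were AT2G15780 (4.29), AT3G29970 (6.13), AT1G14960 (-2.42) and AT5G17340 (-2.65). Without control replicate 2 the lost call was AT3G03670 (4.93), and kept but moved by over 1.5-fold were AT2G15780 (6.11), AT3G29970 (4.20), AT1G52070 (-4.68), AT1G14960 (-4.63), AT5G44020 (-4.10), AT1G30870 (-3.98), AT5G17340 (-3.83) and AT5G17820 (-3.75). Without 30 h replicate 1 the lost calls were AT3G03670 (4.48), AT1G52070 (-3.58), AT1G14960 (-3.15), AT5G44020 (-3.07), AT1G30870 (-2.95), AT1G67330 (-3.22), AT3G49960 (-3.07) and AT5G17820 (-2.99), and kept but moved by over 1.5-fold were AT2G15780 (6.02), AT1G26240 (4.31) and AT5G17340 (-2.65). Without 30 h replicate 2 the lost calls were AT3G03670 (5.74), AT1G52070 (-4.20), AT3G49960 (-3.46) and AT5G17820 (-3.28), and kept but moved by over 1.5-fold were AT2G15780 (4.38), AT1G26240 (5.63) and AT5G17340 (-3.83). AT3G03670 was also lost without either 6 h array (adjusted p = 0.0531 and 0.0529).

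**Figure D2:**
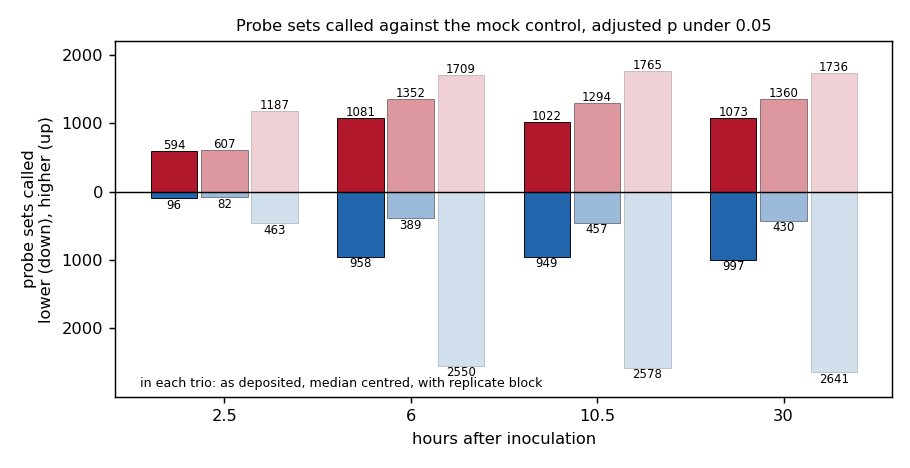
Number of probe sets called against the mock control (adjusted p under 0.05) by hours after inoculation, higher above the zero line and lower below it, for values as deposited, after median centring and with the replicate block. As deposited, 690 probe sets were called at 2.5 h, 2039 at 6 h, 1971 at 10.5 h and 2070 at 30 h.

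From 2.5 h to 6 h the peroxidase AT5G06730 rose from 71.2 ± 0.1 to 590.0 ± 16.6 (log2 change 2.80, SE 0.20, adjusted p = 0.00532). AT3G56500 rose from 91.9 ± 7.2 to 531 ± 15.4 (2.34, SE 0.26, adjusted p = 0.0385), AT1G22890 from 54.7 ± 12.8 to 264 ± 7.2 (2.00, SE 0.24, adjusted p = 0.0451) and AT5G37840 from 32.2 ± 9.6 to 174 ± 28.8 (1.99, SE 0.25, adjusted p = 0.0457). These 4 are the called probe sets that name 1 gene; the other 5 of the 9 called, all of them higher at 6 h, have no name in the table. The blocked model called 209 (117 higher and 92 lower). The count was 0 without either 2.5 h array or without 6 h replicate 1, 3 without 6 h replicate 2, 4 without either 30 h array, and 5 without either control array or either 10.5 h array. Of the 4 named calls, that of AT5G06730 was lost without either 2.5 h array (adjusted p = 0.113 and 0.0906) or without 6 h replicate 1 (0.0672). AT3G56500 was lost without any 1 of the control, 2.5 h, 6 h or 10.5 h arrays (0.0557 to 0.354), and AT1G22890 and AT5G37840 without any 1 of the 10 arrays (0.0557 to 0.387). Quantile normalisation, no filter on dim probe sets and no intensity trend each ended the calls of AT1G22890 and AT5G37840, and a pseudocount of 1 also that of AT3G56500.

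Between 6 h and 10.5 h no probe set was called by limma, 239 had an unadjusted p under 0.05, and the blocked model called 2, both lower. The 5 named by the smallest p did not pass. GI, a component of the circadian clock whose transcript cycles with the day, was at 494 ± 99.0 at 6 h and 101 ± 24.4 at 10.5 h (log2 change -2.12, SE 0.32, adjusted p = 0.973, blocked 0.0182). AT4G15680 was at 34.4 ± 11.9 and 1.6 ± 0.5, and AT5G06730 at 590.0 ± 16.6 and 1235 ± 25.2. SBE2.2, a starch branching enzyme, was at 40.4 ± 18 and 7.4 ± 5.6, and AT2G28200 at 12.3 ± 3.2 and 37.9 ± 4.5. Between 10.5 h and 30 h limma again called 0 probe sets, with 1046 at an unadjusted p under 0.05, and the blocked model called 17 (13 higher and 4 lower). Of the 5 with the smallest p, none of which passed, AT5G52390 was at 53.6 ± 3.9 and 563 ± 281 (adjusted p = 0.0879, blocked 0.00823) and AT3G19030 at 587 ± 6.8 and 77.3 ± 27.5 (adjusted p = 0.0879, blocked 0.0124). GI was back at 488 ± 6.0 at 30 h (adjusted p = 0.255, blocked 0.0123). BETA-VPE, a vacuolar processing enzyme, was at 37.6 ± 11.5 and 111 ± 8.6 (blocked adjusted p = 0.0641), and ATC at 26.0 ± 32.1 and 351 ± 182 (blocked adjusted p = 0.0273). Without either 2.5 h array, 2 probe sets were called between 10.5 h and 30 h, 1 higher and 1 lower.

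A direct comparison of 30 h with 2.5 h, added after the data were seen, gave calls in both directions. The peroxidase AT5G06730 (log2 change 4.84, SE 0.20, adjusted p = 5.19e-05), AT2G15780 (5.07), AT5G52390 (4.12), CYP71B22 (3.75) and AT1G62760 (3.52) were higher at 30 h. AT2G44370 was at 56.4 ± 36.5 in control, 1159 ± 121 at 2.5 h and 19.7 ± 26.7 at 30 h (-5.27, SE 0.64, adjusted p = 0.0116). AT5G43520 was at 217 ± 48.6, 2592 ± 113 and 134 ± 80.6 (-4.23, SE 0.54, adjusted p = 0.014). AT2G44380 changed by -3.85, and the peroxidase AT5G64120 by -3.55, from 1664 ± 2.3 to 141 ± 90.0. AT2G21045 changed by -3.64 and was at 866 ± 82.6 in control, 1529 ± 639 at 2.5 h and 104 ± 31.9 at 30 h. These genes were picked by the rule used between successive times. As in the comparisons with control, time of day is not told apart from time after inoculation here. In all, 218 probe sets were called, 109 higher and 109 lower at 30 h. Of the 109 lower, 55 had been called higher at 2.5 h against control and 7 were called higher at 30 h against control. The blocked model called 1610 (642 higher and 968 lower). Median centring gave 216 higher and 84 lower, and scaling on the spike-ins 60 higher and 13241 lower. The count was 12 without 2.5 h replicate 1, 74 without 2.5 h replicate 2, 134 without either 6 h array, 101 without either 10.5 h array, 16 without 30 h replicate 1 and 29 without 30 h replicate 2. Of the 10 named calls those of AT5G06730 and AT5G52390 held whichever array was left out. Without 2.5 h replicate 1 the other 8 were lost: AT2G15780 (4.03), CYP71B22 (4.21), AT1G62760 (2.69), AT2G44370 (-5.17), AT5G43520 (-4.19), AT2G44380 (-3.69), AT2G21045 (-3.21) and AT5G64120 (-3.55). Without 2.5 h replicate 2 the lost calls were CYP71B22 (3.3), AT1G62760 (4.34), AT5G43520 (-4.28), AT2G44380 (-4.01) and AT5G64120 (-3.55), and AT2G15780 moved to 6.11. Without 30 h replicate 1 the same 8 were lost: AT2G15780 (5.89), CYP71B22 (3.39), AT1G62760 (3.80), AT2G44370 (-4.42), AT5G43520 (-3.66), AT2G44380 (-3.29), AT2G21045 (-3.37) and AT5G64120 (-2.93). Without 30 h replicate 2 the lost calls were AT2G15780 (4.25), CYP71B22 (4.12), AT1G62760 (3.24), AT2G44380 (-4.41) and AT5G64120 (-4.17), and AT2G44370 moved to -6.12. AT2G15780 was also lost without either 10.5 h array (adjusted p = 0.0503 and 0.0508), and AT1G62760 without any 1 of the 6 h and 10.5 h arrays (0.0623 to 0.0741).

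**Figure D3:**
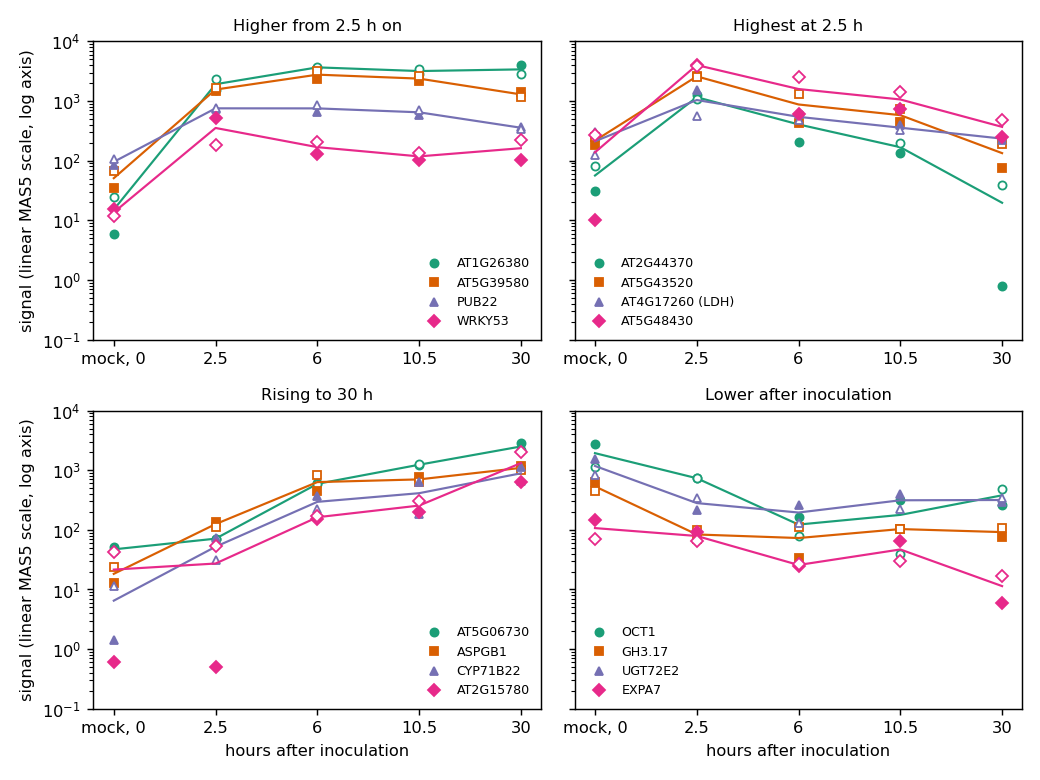
Signal of 16 genes on a log axis by hours after inoculation, with 1 point per array (filled, replicate 1; open, replicate 2) and lines through the group means. AT1G26380 is at 15.2 in control and 1915 at 2.5 h, AT2G44370 is at 1159 at 2.5 h and 19.7 at 30 h, AT5G06730 reaches 2498 at 30 h, and OCT1 is at 1931 in control and 123 at 6 h.

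Against the shared control, genes called at one time were largely called at the next. Between 6 h and 10.5 h, 911 probe sets were called higher and 615 lower at both times, against 69.4 and 57.1 for independent lists, and 0 went in opposite directions. For 2.5 h and 6 h the numbers were 496 higher and 83 lower (40.3 and 5.8 for independent lists), for 10.5 h and 30 h 811 and 483 (68.9 and 59.4), and for 2.5 h and 30 h 434 and 63 (40.0 and 6.0), with 1, 1 and 2 probe sets in opposite directions. At all 4 times 429 probe sets were called higher and 63 lower, and 3199 were called at least once. The 4 comparisons share the control arrays, so part of the excess may come from these. In 20 simulations of unchanged groups 0 calls were shared, but with no change in them this does not measure that part. In a test added after the data were seen, each time of a pair was given a control array of its own, assumed to vary like the other groups. Control replicate 1 was first given to 6 h and control replicate 2 to 10.5 h. Then 520 probe sets were called higher and 100 lower at both times (39.3 and 13.2 for independent lists). These were among 2248 calls at 6 h and 763 at 10.5 h. With the control arrays exchanged, 536 and 107 were shared (43.2 and 12.2), among 817 and 2188 calls. Shared falls were fewest between 2.5 h and 30 h, with 23 and 9 (0.8 and 4.4 for independent lists), and 0 and 8 probe sets there went in opposite directions. The F-test over the 4 comparisons called 1305 probe sets, and 4091 with the block. It called 504 without control replicate 1, 857 without 6 h replicate 1, 839 without 10.5 h replicate 2, 619 and 726 without 30 h replicate 1 or 2, and 825 without both 30 h arrays.

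Some genes of pattern-triggered signalling, the response to molecules shared by many microbes, rose; 4 of the 24 genes of this list were tested. The U-box E3 ligase genes PUB22, PUB23 and PUB24, which dampen this response, were called higher at all 4 times. PUB22 was at 95.6 ± 14.9 in control and 754 ± 9.1 at 2.5 h (log2 change 2.79, SE 0.22, adjusted p = 0.000418). PUB23 was at 157 ± 41.0 and 1090 ± 238 (2.68, SE 0.25, adjusted p = 0.000831) and PUB24 at 87.2 ± 25.1 and 316 ± 54.7 (1.70, SE 0.26, adjusted p = 0.0077). At 30 h PUB22 was at 357 ± 16.9 and PUB23 at 346 ± 26.8. BIK1, a receptor-associated kinase, was at 326 ± 154 in control and 767 ± 103 at 6 h and was called there (1.27, SE 0.31, adjusted p = 0.0308). Of the 4 tested members 3, 4, 3 and 3 rose at 2.5, 6, 10.5 and 30 h; adjusted over the list alone and with the block, 4 rose at each time. The median member stood 2.31, 2.35, 2.12 and 1.5 above the median of all probe sets. The list was shifted up with adjusted p = 1.8e-06, 2.02e-05, 5.3e-05 and 0.000612, and with adjusted p = 0.294, 0.294, 0.294 and 0.315 with an estimated correlation. From 10.5 h to 30 h it was shifted down (adjusted p = 0.0136, and adjusted p = 0.315 with an estimated correlation), while no member was called over all genes and 2 were, adjusted over the list alone. Leaving out 1 array ended some calls. PUB24 lost that at 2.5 h without 2.5 h replicate 1 (adjusted p = 0.0664) and that at 30 h without 30 h replicate 1 (0.064). PUB23 lost that at 30 h without control replicate 2 (0.0776) or 30 h replicate 1 or 2 (0.112 and 0.126). BIK1 lost its call without control replicate 1 (0.126), 6 h replicate 1 or 2 (0.093 and 0.138) or 30 h replicate 1 or 2 (0.0534 and 0.053).

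The defence regulators WRKY53, WRKY22 and WRKY6 also rose. WRKY53 was at 13.6 ± 2.7 in control and 354 ± 238 at 2.5 h (log2 change 3.48, SE 0.47, adjusted p = 0.00474). WRKY22 was at 35.2 ± 11.9 and 336 ± 73.4 (2.79, SE 0.58, adjusted p = 0.031), and WRKY6 at 113 ± 46.7 and, at 10.5 h, 494 ± 111 (2.01, SE 0.32, adjusted p = 0.00537). At each time 2 of the 3 rose, with the block 3; adjusted over the list alone 3 rose at 2.5, 6 and 10.5 h and 2 at 30 h. The list was shifted up at 2.5, 6, 10.5 and 30 h with adjusted p = 0.001, 0.00478, 0.0102 and 0.0125, and with adjusted p = 0.315 with an estimated correlation at each time. WRKY22 lost its call at 2.5 h without any 1 of the control or 2.5 h arrays (adjusted p from 0.0783 to 0.153). WRKY53 lost that at 6 h without 6 h replicate 2 (0.0641), that at 10.5 h without any 1 of the control or 10.5 h arrays (0.0603 to 0.125) and that at 30 h without control replicate 1 or 30 h replicate 2 (0.0567 and 0.0809). WRKY6 lost that at 30 h without control replicate 1 or either 30 h array (0.0606 to 0.0672). The change of WRKY53 at 2.5 h was 2.77 without 2.5 h replicate 1 and 4.19 without 2.5 h replicate 2, and its call was kept.

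Some of the secondary metabolism and detoxification genes that could be named rose. CCR2, a cinnamoyl-CoA reductase, was at 114 ± 8.0 in control and 1023 ± 255 at 2.5 h (log2 change 2.98, SE 0.24, adjusted p = 0.000493). HCT, another enzyme of lignin synthesis, was at 638 ± 233 and 1103 ± 118 and was not called. IGPS (AT2G04400), an enzyme of tryptophan synthesis, was at 280 ± 5.7 in control and 2223 ± 281 at 6 h (2.91, SE 0.41, adjusted p = 0.00312). UGT74B1, a glucosyltransferase of glucosinolate synthesis, was at 197 ± 74.5 and 915 ± 36.8 (2.17, SE 0.30, adjusted p = 0.00295). Both were called at all 4 times, as was CCR2. DFR, the tested gene of flavonoid synthesis, stayed between 7.6 ± 4.9 and 19.4 ± 0.2 and was not called. Of 4 detoxification genes the glucosyltransferase UGT73B4 rose at 2.5 h (1.71, SE 0.27, adjusted p = 0.00878), and UGT73B4 and UGT73B5 rose at 6, 10.5 and 30 h, with UGT73B5 at 137 ± 77.1 in control and 555 ± 122 at 30 h. The glutathione transferase genes GSTU22 and GSTU25 were at 455 ± 176 and 257 ± 218 in control and 363 ± 80.7 and 538 ± 258 at 2.5 h and were not called. With the block GSTU25 was called at 2.5 h (adjusted p = 0.0422) and GSTU22 was lower at 6 h (adjusted p = 0.00518). This list was shifted up at 2.5 h (adjusted p = 0.0471, and adjusted p = 0.315 with an estimated correlation); adjusted over the list alone 2, 3, 2 and 2 members passed at the 4 times. The calls of CCR2 held whichever array was left out. At 2.5 h that of IGPS (AT2G04400) was lost without either control array, 2.5 h replicate 2 or any 1 of the 10.5 and 30 h arrays (adjusted p from 0.0518 to 0.113), and at 30 h without 30 h replicate 1 (0.0524). Its change at 2.5 h was 2.00, and 2.74 without 2.5 h replicate 1. UGT74B1 lost that at 2.5 h without control replicate 2 or 2.5 h replicate 2 (0.0773 and 0.106), that at 10.5 h without either 10.5 h array (0.0663 and 0.0619) and that at 30 h without 30 h replicate 1 (0.0974). UGT73B4 lost that at 2.5 h without control replicate 1 or 2.5 h replicate 1 (0.051 and 0.0736). UGT73B5 lost that at 6 h without control replicate 1 or either 6 h array (0.0612 to 0.085), that at 10.5 h without control replicate 1 or 10.5 h replicate 2 (0.0582 and 0.102) and that at 30 h without 30 h replicate 1 (0.0819).

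Hormone-related lists were thinly covered. OPCL1, an enzyme of jasmonate synthesis, rose at each time, from 105 ± 17.2 in control to 341 ± 53.5 at 30 h (log2 change 1.56, SE 0.21, adjusted p = 0.00263). GRX480, a glutaredoxin of the salicylic acid response, was called at 6 h and 30 h, where it was at 546 ± 229 against 108 ± 36.8 in control (2.15, SE 0.39, adjusted p = 0.0104). SAG101, a partner of EDS1, was called at 2.5 h (0.98, SE 0.21, adjusted p = 0.0323) and 10.5 h (0.92, SE 0.21, adjusted p = 0.0235), and after median centring also at 6 h and 30 h (adjusted p = 0.0158 and 0.018). The defensin gene LCR67 (PDF1.1) was called higher at 6, 10.5 and 30 h, at 35.1 ± 7.9 at 6 h against 0.9 ± 0.3 in control (1.58, SE 0.29, adjusted p = 0.00984), and at 2.5 h with the block (adjusted p = 0.0116). EIN3, the tested ethylene gene, was at 520 ± 207 in control and 675 ± 70.9 at 10.5 h and was not called. Of the 3 tested auxin genes GH3.3, which conjugates auxin, was called higher at 2.5 h, at 48.9 ± 5.1 against 2.2 ± 2.4 (1.84, SE 0.25, adjusted p = 0.00474), while WES1 (GH3.5) and LBD16 were not called. With the block GH3.3 was also higher at 10.5 h (adjusted p = 0.0332) and LBD16 lower at 6 h and 10.5 h (adjusted p = 0.0456 and 0.0382). The auxin list was shifted down from 2.5 h to 6 h (adjusted p = 0.0136, and adjusted p = 0.315 with an estimated correlation), with no member called over all genes and 2 adjusted over the list alone. OPCL1 lost its call at 2.5 h without control replicate 2 or either 2.5 h array (adjusted p from 0.0861 to 0.134). GRX480 lost that at 6 h without control replicate 1 or 6 h replicate 1 (0.129 and 0.134) and that at 30 h without control replicate 1 or 30 h replicate 1 (0.07 and 0.091). SAG101 lost that at 2.5 h without any 1 of the 10 arrays (0.0508 to 0.183) and that at 10.5 h without any 1 of the control or 10.5 h arrays (0.0582 to 0.13). LCR67 lost that at 6 h without 6 h replicate 1 (0.0737), that at 10.5 h without control replicate 1 or 10.5 h replicate 1 (0.0582 and 0.0589) and that at 30 h without control replicate 1 or either 30 h array (0.0516 to 0.0819).

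Stress and housekeeping lists gave fewer calls. AT4G17260, lactate dehydrogenase, was called higher at 2.5 h, at 1040 ± 675 against 211 ± 123 in control (log2 change 2.16, SE 0.48, adjusted p = 0.0418). That call was lost without control replicate 2 (1.58), without 2.5 h replicate 1 (1.46) and without any 1 of the 6, 10.5 or 30 h arrays (2.16); without 2.5 h replicate 2 it was 2.87 and kept. The low-oxygen list was shifted up at 6 h (adjusted p = 0.034, and adjusted p = 0.315 with an estimated correlation) and, with the block, at 2.5 h (adjusted p = 0.0441, and adjusted p = 0.386 with an estimated correlation). At 6 h none of its 3 members was called over all genes, 3 were adjusted over the list alone, and 3 with the block. The others were the regulator HRA1 (AT3G10040), at 86.7 ± 91.4 in control and 517 ± 212 at 2.5 h, and pyruvate decarboxylase PDC2, at 562 ± 217 and 573 ± 28.6. These are values of 2.5 h, and at 6 h the median member changed by 1.41 (log2). COR47, a dehydrin, was lower at 30 h, at 400.0 ± 344 against 1769 ± 97.1 (-2.40, SE 0.52, adjusted p = 0.0204), a call lost without either control array (adjusted p = 0.084 and 0.052) or without 30 h replicate 1 (0.0524). Without 30 h replicate 2 it was -3.37 and kept. LTI30, COR15A and COR15B were not called, and adjusted over the list alone 1 member passed at 30 h. With the block COR47 was also lower at 10.5 h (adjusted p = 0.0414), and COR15A was lower at 10.5 h and 30 h (adjusted p = 0.0153 and 0.0302). The vacuolar processing enzyme GAMMA-VPE was lower at 2.5 h, at 849 ± 97.1 against 1793 ± 71.9 (-1.07, SE 0.20, adjusted p = 0.0194), and at 6 h and 10.5 h, where median centring ended the call (adjusted p = 0.169 and 0.104). Its call at 2.5 h was lost without any 1 of the control or 2.5 h arrays (adjusted p from 0.0536 to 0.116), that at 6 h without any 1 of the 10 arrays (0.058 to 0.162) and that at 10.5 h without any 1 of the arrays other than those of 2.5 h (0.0522 to 0.134). ALPHA-VPE was not called. The clock gene GI was lower at 10.5 h, at 101 ± 24.4 against 802 ± 301 (-2.77, SE 0.32, adjusted p = 0.00131). The heat shock gene HSP17.6C (AT1G53540) was at 22.7 ± 20.7 in control and 55.9 ± 14.6 at 30 h and was not called. None of the 5 sugar transporters of the SWEET family was called; SWEET2 was at 153 ± 150 in control and 498 ± 201 at 10.5 h (blocked adjusted p = 0.00196). With the block SWEET2 was also higher at 6 h and 30 h (adjusted p = 0.0277 and 0.00215), and SWEET13 and SWEET16 were lower at 30 h (adjusted p = 0.0335 for each). Adjusted over the list alone 3 members passed at 30 h. None of 3 xyloglucan endotransglucosylases was called; XTH18 was at 130 ± 52.1 in control and 583 ± 359 at 2.5 h (blocked adjusted p = 0.00229). The block also called XTH18 higher at 6 h and 10.5 h (adjusted p = 0.0024 and 0.0159), and XTH19 lower at 10.5 h and 30 h (0.0244 and 0.0041) and XTH20 at 30 h (0.0307). Adjusted over the list alone 1 xyloglucan endotransglucosylase passed at 2.5 h, 1 at 6 h and 2 at 30 h. With the block, this list and the abscisic acid list were shifted down from 6 h to 10.5 h (adjusted p = 0.0201 and 0.0404), and with adjusted p = 0.471 with an estimated correlation for each. Without the block neither was called (adjusted p = 0.0989 and 0.122). The cell cycle genes AUR1, AUR2 and MCM7 were not called, with AUR1 at 61.2 ± 37.9 in control and 28.6 ± 2.2 at 30 h; with the block MCM7 was lower at 6 h (adjusted p = 0.0447). Neither were the reference genes TIP41, UBC21 and SAND, with UBC21 at 237 ± 55.0 and 219 ± 20.9. The lists for nitrate uptake, aquaporins, susceptibility genes, endodermis, vascular tissue and root tip had 0 members that the table names.

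Markers of cell types were few. The root hair expansins EXPA7 and EXPA18 were lower at 6 h and 30 h. EXPA7 was at 107 ± 53.2 in control, 25.8 ± 1.0 at 6 h (log2 change -1.49, SE 0.38, adjusted p = 0.0374) and 11.4 ± 7.7 at 30 h (-2.13, SE 0.38, adjusted p = 0.00994), and EXPA18 at 173 ± 124, 25.3 ± 2.1 and 17.9 ± 5.1. Adjusted over the list alone both passed at 6, 10.5 and 30 h, and after median centring the calls at 6 h were lost (adjusted p = 0.0743 and 0.0663). At 6 h both calls were lost without control replicate 1, either 6 h array or either 30 h array (adjusted p from 0.0531 to 0.19), and that of EXPA18 also without either 2.5 h array (0.0524 and 0.0522). At 30 h both were lost without control replicate 1 or 30 h replicate 1 (0.0621 to 0.141) and that of EXPA18 without 30 h replicate 2 (0.0858). Without control replicate 2 the change of EXPA18 was -2.74 at 6 h and -3.04 at 30 h, with all arrays -2.02 and -2.31. RCA and LHCB4.1, markers of green shoot tissue, were at 239 ± 212 and 308 ± 263 in control, with replicates far apart, and at 82.2 ± 26.3 and 195 ± 178 at 30 h. They were not called, but with the block they were lower at 10.5 h (adjusted p = 0.0242 and 0.00429) and at 30 h (adjusted p = 0.0437 and 0.0238). Of 371 values of list members over all lists and planned comparisons, 62 passed over all genes and 104 adjusted over their list alone. Over all 70 list tests, 12 were called at the preset correlation, 0 with an estimated correlation and 15 by fry. Fry called the pattern-triggered, WRKY and detoxification lists at 2.5, 6, 10.5 and 30 h against control. For detoxification its adjusted p was 0.0214, 0.0214, 0.0176 and 0.0196. It also called the auxin list at 2.5 h and from 2.5 h to 6 h, and the low-oxygen list at 6 h.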

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

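The tests of dim probe sets, nuclear DNA, the amount of plant mRNA and RNA integrity, and the comparison of 30 h with 2.5 h, were chosen after the result was seen. Differences between inoculated times were called for 9 probe sets from 2.5 h to 6 h and for 218 from 2.5 h to 30 h, by a test of the difference itself.

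Tested probe sets of pseudogenes and of plastid-encoded genes were higher at 2.5 h than in control by their medians, most so the dim ones. Of the brighter 35 plastid-encoded probe sets 25 were higher and 10 lower, atpB (-1.04) and petB (-0.42) among the latter. A rise of dim probe sets in general is argued against as the whole of it for the dimmer 34 of the 69 plastid-encoded probe sets, which exceeded nuclear protein-coding probe sets of like control level by 1.54 (log2). It remains open for the brighter 35, which exceeded them by 0.35, between the bounds of 0.25 and 0.5 set for this test. In both parts 0 of 10000 random lists of like level were as high. Such lists take no account of plastid-encoded probe sets moving together, so they do not measure the spread between arrays. For pseudogenes it remains open, and it is not shown to suffice together with the filter. Those that passed the filter exceeded nuclear protein-coding probe sets of like control level that also passed it by 0.55. Here too 0 of 10000 random lists of like level were as high. Only 115 of the 923 pseudogene probe sets passed the filter on the mean of all 10 arrays, and one dim in control passes only if other arrays are higher. Without the filter the 923 had a median change of 0.23, against 0.31 for nuclear protein-coding probe sets of like control level. The rise among tested pseudogenes is therefore not taken as a property of the class. Organelle nucleic acid carried over in general remains open, since 16 mitochondrial probe sets exceeded like-level sets by only 0.29. Nuclear DNA carried over remains open too, since the 923 pseudogene probe sets stood 0.22 above all probe sets without the filter but lie near the floor (median control signal 2.2). Early transcription after inoculation may also be a source, but no biological explanation was tested.

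The median tested probe set was lower than in control at each inoculated time, with a change of -0.12 at 2.5 h and larger ones from 6 h on. The authors' scaling of each array to 1 trimmed mean remains open. Arrays were rescaled on the probe sets that the F-test did not call, which include some called at single times. The median shift was then -0.08 at 6 h and -0.05 at 30 h. That set was picked by the outcome and holds 21441 probe sets, most of the array, so scaling on it draws the median towards 0 whatever the cause. Less plant mRNA in the labelled RNA remains open too, since the spike-in signal at 6 h was 1.01 times that of control. At 2.5, 10.5 and 30 h, which the test did not cover, it was 0.74, 1.09 and 1.75 times that of control. Both 2.5 h arrays (372 and 370) lay below both control arrays (445 and 553). A smaller pool of plant transcripts after infection was not tested apart from less plant mRNA in the labelled RNA.

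Genes called against control could follow a change of RNA integrity, since the GAPDH ratio rose with time (1.67 at 6 h, 2.18 at 10.5 h, 2.54 at 30 h, against 1.37 in control) while the actin ratio did not follow it at each time (2.73 at 2.5 h, 3.08 at 6 h, 2.75 at 10.5 h and 4.17 at 30 h, against 2.93). Within each replicate number control and 2.5 h had similar GAPDH ratios (1.23 and 1.24 in replicate 1, 1.5 and 1.6 in replicate 2), so genes called without such a pair were looked up in it, and the smaller median shift of the 2 pairs is given. Genes called higher had shifted in the called direction by 2.06, 1.00, 0.96 and 0.82 (called at 2.5, 6, 10.5 and 30 h), which argues against integrity as the whole cause of the rises. Genes called lower at 2.5 h had shifted by 0.38 in replicate 1 (10 genes, 90% in the called direction) and by 1.14 in replicate 2 (17 genes, 94.1%), with lower quartiles of 0.16 and 0.99. By the bounds of this form that argues against integrity as the whole cause of the falls at 2.5 h, though on few genes. An earlier form of the test had asked for a median over 0.5 and 20 genes, which these values do not meet. The bounds used were written after results had been seen, so the verdict on these falls is weak. Genes called lower at 6, 10.5 and 30 h had shifted by 0.91, 0.70 and 0.61 in replicate 1. The lower quartiles there were 0.55, 0.41 and 0.22. In replicate 2 the shifts were 0.27, 0.25 and 0.23, with lower quartiles below 0, so for these falls integrity remains open. A fall that begins after 2.5 h would give such small values as well. A first form of this test, on replicate 1 alone with rises and falls pooled, had given 2.91, 1.65, 1.57 and 1.51 and hid the weaker values of the falls.

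The hybridisation spike-ins averaged 874 at 30 h, above both control arrays (mean 499). The ubiquitin ratio was 1.5 at 30 h, above both control arrays (mean 1.31). The 25S ribosomal RNA probe set was at 818 at 30 h, above both control arrays (mean 612), while the 2.5 h and 6 h replicates were at 2464 and 216 and at 3594 and 203.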

How the results depend on the processing

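Spike-in scaling, median centring with the block, leaving out the 30 h or 2.5 h arrays, leaving out plastid-encoded genes and pseudogenes, splitting the controls, and every value for 30 h against 2.5 h and for the families were chosen after seeing the data. Of 2466 values of named genes under the alternatives (130 called values), 2170 kept direction and call, 296 kept direction only and 0 reversed. For genes named by the rule, whose arrays do not overlap between groups, leaving out 1 array cannot reverse a change. The block leaves each change as it is, so 0 reversals were largely fixed in advance. The replicate block kept all 130 and moved the counts below. Of 371 values of list members in the 7 planned comparisons it called 106 against 62, with 44 gained and 0 lost, and only part of the 44 is given with the results. Without control replicate 1, 52 of the 130 lost their call, and without 30 h replicate 1, 35. Without the filter on dim probe sets 11 of 130 lost their call. Except where a reason is given, the cause was not tested.

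With the replicate block the counts at 2.5, 6, 10.5 and 30 h were 1650, 4259, 4343 and 4377, those from 2.5 h to 6 h, 6 h to 10.5 h, 10.5 h to 30 h and 2.5 h to 30 h 209, 2, 17 and 1610, the F-test 4091, and the overlaps (2.5 and 6 h, 6 and 10.5 h, 10.5 and 30 h, 2.5 and 30 h) 1304, 3393, 3062 and 1076, against 579, 1526, 1294 and 497. With block and median centring these were 1603, 3383, 3668 and 3664, then 301, 3, 16 and 1735, 3625, and 1276, 2770, 2521 and 1037. With the control arrays split between the times of a pair, the overlaps were 345, 620, 559 and 285 with control replicate 1 for the earlier time and 317, 643, 550 and 262 with replicate 2. With only probe sets that name exactly 1 gene, and so fewer genes tested, there were 379, 1029, 992 and 1044, 4 from 2.5 h to 6 h, 125 from 2.5 h to 30 h, and 681 by the F-test. With only the 4 arrays of the groups compared, and so fewer samples, there were 188, 690, 630 and 1048, and 0 from 2.5 h to 6 h. On the spike-ins there were 987 at 6 h, 999 at 10.5 h and 8594 at 30 h, 4 from 2.5 h to 6 h, 2 from 10.5 h to 30 h, 13301 from 2.5 h to 30 h, 8279 by the F-test, and overlaps of 763 (6 and 10.5 h) and 761 (10.5 and 30 h). A pseudocount of 1 gave 2 from 2.5 h to 6 h and 137 from 2.5 h to 30 h. Without the 30 h arrays there were 4 from 2.5 h to 6 h and 825 by the F-test, and without the 2.5 h arrays 2 from 10.5 h to 30 h. With an estimated correlation 0 gene lists (12 at the preset one) and 0 families (4) were called. Lists with an estimated correlation below the preset 0.01 lost their call too, so correlation alone does not account for the loss. With an estimated correlation, camera takes its p from a t distribution with the residual degrees of freedom (5 without the block). With a preset one it uses many more, so the estimated form has less power here. A list that lost its call is therefore not shown to hold correlated genes. Unadjusted camera p went from 0.00195 to 0.026 for the auxin list from 2.5 h to 6 h (correlation -0.093). For the detoxification list at 2.5 h (-0.056) it went from 0.00807 to 0.0434.

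Leaving out 1 array at a time, with a lone array assumed to vary like the other groups, gave 292 to 619 at 2.5 h, 722 to 2241 at 6 h, 637 to 2190 at 10.5 h, 514 to 2356 at 30 h, 0 to 5 from 2.5 h to 6 h, 0 to 0 from 6 h to 10.5 h, 0 to 2 from 10.5 h to 30 h, 12 to 293 from 2.5 h to 30 h, 504 to 1153 by the F-test, and 10 to 15 gene lists. The overlaps were 269 to 492, 607 to 1821, 459 to 1641 and 253 to 435.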

Other observations

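The gene groups here were chosen after the data were seen. Among genes encoded in the plastid genome, those dim in mock roots stood higher at 2.5 h. Of 69 probe sets 9 were called higher at 2.5 h and 0 lower, with a median log2 change of 0.87 (quartiles 0.13 and 1.46). The dimmer 34, with control signals up to 99.2, had a median change of 1.51 (34 higher and 0 lower) and held the 9 calls. The brighter 35 had a median change of 0.13 (25 higher and 10 lower), with 0 called by limma. Of these, atpB was at 782 ± 286 in control and 368 ± 117 at 2.5 h (-1.04, adjusted p = 0.134), petB at 978 ± 489 and 704 ± 273, and psbM at 2557 ± 907 and 2036 ± 1332. The photosystem II gene psbB was at 14.0 ± 17.9 (SD, n = 2) in control, 196 ± 83.3 at 2.5 h and 12.2 ± 12.5 at 30 h. The plastid RNA polymerase gene rpoB was at 7.0 ± 8.0, 74.4 ± 24.3 and 10.6 ± 2.8, and the NADH dehydrogenase-like complex genes ndhK and ndhG were at 11.2 ± 1.3 and 28.0 ± 12.6 in control and 85.9 ± 15.9 and 282 ± 36.1 at 2.5 h. At 6 h no plastid-encoded probe set was called by limma and the median change was 0.09. This was still 0.37 above nuclear protein-coding probe sets of like control level, with 0 of 10000 random lists of like level as high. Such lists take no account of plastid-encoded probe sets moving together. The plastid-encoded median signals were 72.8 and 153.6 on the 6 h arrays and 74.3 and 131.4 on the control arrays. Whether 0.37 exceeds that spread was not tested. Of the 115 probe sets of pseudogenes that passed the filter, 18 were called higher and 1 lower at 2.5 h. Their median change of 1.03 is raised by the filter, which keeps a probe set dim in control only if other arrays are higher. It was 0.48 for nuclear protein-coding probe sets of like control level that passed the same filter. Without it, the 923 pseudogene probe sets of the array had a median change of 0.23, which was 0.08 below nuclear protein-coding probe sets of like control level.

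Families of at least 8 tested genes that share a symbol stem were also tested, 19 families in 133 tests. Among 11 beta-glucosidase genes (BGLU), which split glucose from stored conjugates, 3 were called higher and 1 lower at 30 h. BGLU27 was at 5.0 in control and 547 at 30 h (log2 change 4.75, adjusted p = 0.000105), BGLU45 at 16.2 and 377 (3.65, adjusted p = 0.000404) and BGLU46 at 210.3 and 2028 (3.31, adjusted p = 0.00598), while BGLU44 was at 534 and 181 (-1.45, adjusted p = 0.0475). The family was shifted up at 30 h (adjusted p = 0.0165, and adjusted p = 0.652 with an estimated correlation; 0.058 after median centring), from 2.5 h to 6 h (adjusted p = 0.0152, and adjusted p = 0.652 with an estimated correlation) and from 10.5 h to 30 h (adjusted p = 0.0165, and adjusted p = 0.652 with an estimated correlation). From 2.5 h to 6 h and from 10.5 h to 30 h no BGLU member was called. The 8 autophagy genes (ATG) were shifted up from 2.5 h to 6 h (adjusted p = 0.0165, and adjusted p = 0.74 with an estimated correlation), with no member called. Of 37 glycosyltransferase genes (UGT), 5 were called higher and 1 lower at 2.5 h, and the family was not called (adjusted p = 0.0569). With the block the BGLU family was also called at 6 h (adjusted p = 0.0421, and adjusted p = 0.903 with an estimated correlation; 0.0576 without the block). The 9 glutathione transferase genes (GSTU) were shifted down from 2.5 h to 6 h with the block (adjusted p = 0.0259, and adjusted p = 0.903 with an estimated correlation) and after median centring (0.0342), but not as deposited (0.102), with no member called. No family was called with an estimated correlation.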
